A study of Mus musculus with 6 samples.

How the data were processed

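The study transplanted hearts between mice and collected CD45-positive cells, the leukocytes, on day 6. Hearts of BALB/c donors placed in C57BL/6 recipients formed the allograft group, a full mismatch of the major histocompatibility complex (MHC). Hearts of C57BL/6 donors placed in C57BL/6 recipients formed the matched isograft group. Per the labels, 6 libraries were made with droplet-based 5′ single-cell chemistry. Of these, 3 are gene expression libraries (allograft, spleen of allograft recipients, spleen of isograft recipients) and 3 are T cell receptor libraries with matching titles. Each group has 1 library, pooled from several mice, so no comparison between groups has a replicate error and no p-value was computed.

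The 6 files analysed here are 3 barcode lists and 3 feature lists. Per the submitters' processing notes, the authors used Cell Ranger with the mm10 build; the version, the cell calling, the treatment of doublets and any filter are not given in the sources used here. No doublet caller was run, since a barcode list holds no values to run one on. As deposited, a barcode list holds 1 droplet barcode per line, and a feature list holds a gene identifier, a gene symbol and a feature type per line. All of these are text, with no header and no column of measured values. UMI counts per gene and cell, cell type labels and T cell receptor clonotypes were not analysed here. The planned expression comparisons, which depended on such values, were therefore not made. Sequencing depth is unknown, because a list of barcodes carries no read or UMI number.

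GEO's record ties the lists to the series and to no single sample. Their names refer to a graft, an allo-spleen and an iso-spleen. They are called the graft, allo-spleen and iso-spleen lists by those names, and none was assigned to a library.

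Barcodes were compared after removal of the suffix that every entry carries. The size of the pool from which the lists were drawn was estimated by maximum likelihood for 3 independent lists, and the expected number of shared barcodes followed from that size. The 95% interval of the pool size came from 1000 parametric bootstrap draws. The 95% intervals of the ratios of observed to expected sharing are exact Clopper-Pearson intervals of the shared fraction, with the expected number held fixed. These treat each barcode as an independent trial, though the lists hold distinct barcodes from a finite pool, so their width is approximate. Both kinds of interval cover counting error only. The estimator was tested on simulated lists. For an even pool of 700000 barcodes it returned 100.002% of the true size, with an observed-to-expected ratio of 0.9998 for sharing by all 3 lists. For a pool of 700000 barcodes with uneven yields it returned 98.18% of the true size, and the ratio was 1.0576.

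Gene identifiers were matched without version numbers to the GENCODE M21 annotation of GRCm38, the assembly that mm10 names. The release that the authors used is not given in the sources used here, so gene types and coordinates are those of M21. Before the data were examined, 20 gene lists were fixed: 9 lists of processes, tissues and strain genes, and 11 lists of cell type markers. The genes named are members of these lists, the rule set for files that hold feature lists only. H2-Ea-ps, the H2-Ea pseudogene, and the counts of receptor segments, H2 genes and gene types were added after the data were examined. Alternatives fixed in advance were other pool sizes, subsets of barcodes by first base, distinct barcodes, distinct symbols and matching of symbols without regard to case. The analysis used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and SciPy 1.17.1.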

Results

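The design compares leukocytes that infiltrated a mismatched heart graft with those of spleens of allograft recipients, and spleens of allograft recipients with spleens of isograft recipients, on day 6. The files analysed here give the genes that could be counted and the droplet barcodes listed, and no expression level. Which genes, cell types or T cell clones differed between allograft and spleen, or between allogeneic and isogeneic recipients, was not analysed here. The values below describe the gene set behind those comparisons and the barcode lists.

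The 3 feature lists were identical in content and order. Each held 32285 genes by identifier, all of the type gene expression, so the 3 lists share 1 set of genes. Of these genes, 32235 (99.85%) were found in GENCODE M21 and 50 were not. Of the 32235 found, 31502 carried the same symbol in M21. Symbols were less distinct than identifiers, with 38 symbols standing on more than 1 row. Among M21 protein-coding genes, 21702 of 22028 (98.52%) had a row.

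Of the 99 distinct genes fixed in advance, 97 had a row, each a single one. The lists for the T cell response were complete. All 8 cytotoxicity genes had a row, among them Gzmb (ENSMUSG00000015437, chromosome 14, 56258838 to 56262260), which encodes granzyme B, and Prf1 (ENSMUSG00000037202, chromosome 10, 61297833 to 61304680), which encodes the pore-forming protein perforin. All 7 genes of exhaustion and checkpoints had a row, including Pdcd1 (ENSMUSG00000026285, chromosome 1, 94038305 to 94052553), which encodes the inhibitory receptor PD-1. The 5 genes of naive and memory T cells, the 5 proliferation genes and the 8 interferon response genes had rows as well. Coordinates are on GRCm38.

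The cell type markers were also complete: 10 of 10 for T cells, 4 of 4 for B cells, 4 of 4 for plasma cells and 4 of 4 for NK cells. The 7 markers of monocytes or macrophages, 4 of neutrophils, 5 of dendritic cells and 3 of mast cells or basophils had rows. Markers of cells outside the CD45 gate had rows too: 3 of 3 endothelial, 3 of 3 fibroblast and 3 of 3 erythroid markers. So did 5 of 5 cardiac muscle genes and 4 of 4 red cell haemoglobin genes. A row means only that a gene could be counted, so these counts do not show which cells were captured.

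T cell receptor and antibody segments had rows of their own in the gene expression lists. Symbols starting with Trav, the variable segments of the T cell receptor alpha chain on chromosome 14, took 128 rows, and those starting with Traj, its joining segments, took 60. Variable segments of the beta chain (Trbv, chromosome 6) took 35 rows. The constant genes Trac, Trbc1 and Trbc2 each had 1. Antibody heavy-chain variable segments (Ighv, chromosome 12) took 185 rows and kappa variable segments (Igkv, chromosome 6) took 160. These counts by symbol were not split by gene type and include pseudogenes. In M21, 218 antibody variable segments carry the type IG_V_gene and 158 the type IG_V_pseudogene, and all of them had a row. A further type, IG_LV_gene, held 4 genes, all with a row.

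Genes of the MHC and of antigen presentation mostly had a row. A row names a gene and no allele, so whether BALB/c donor alleles were counted under it, or apart from those of the recipient, was not tested. All 7 genes of the MHC class I and II list, of which Cd74 and B2m lie outside chromosome 17, had a row, including H2-K1 (ENSMUSG00000061232, chromosome 17, 33996017 to 34000347) and H2-D1 (ENSMUSG00000073411, chromosome 17, 35262730 to 35267499), which encode classical class I heavy chains. In all, 34 symbols starting with H2- had a row. The 2 genes of the donor-strain list, H2-L and H2-Ea, had none. H2-L encodes a class I molecule of the H-2d haplotype of BALB/c, and H2-Ea encodes the alpha chain of the class II molecule H2-E, which C57BL/6 mice do not express. M21 holds no gene named H2-L or H2-Ea. It places H2-Ea-ps (ENSMUSG00000036322) at 34341959 to 34344645 on the minus strand of chromosome 17, as a polymorphic pseudogene. By identifier, H2-Ea-ps had no row either. H2-Eb1, the partner beta chain gene, had a row.

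The barcode lists were similar in length. The graft list held 672223 barcodes, the allo-spleen list 623455 and the iso-spleen list 624841. The graft list was 1.0782 times as long as the allo-spleen list, and the iso-spleen list 1.0022 times. With 1 list per name these differences have no replicate check. All entries were 16 bases long, and no entry was repeated within a list.

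Most barcodes recurred across the lists. Of 732317 distinct barcodes, 498489 (68.07%) stood in all 3 lists, 191224 in exactly 2 and 42604 in exactly 1. The barcodes shared by all 3 made up 79.96% of the allo-spleen list, the shortest. The allo-spleen and graft lists shared 574444 barcodes, the graft and iso-spleen lists 575524, and the allo-spleen and iso-spleen lists 536723. Taken as independent, the lists gave an estimated pool of 733687 barcodes (95% interval 733609 to 733765, counting error only). Of this pool the graft list covered 91.62%, the allo-spleen list 84.98% and the iso-spleen list 85.16%. The sharing described below departs from independence, and the simulation with uneven yields returned 98.18% of the true size. The pool may therefore be larger than the interval allows, and the coverage lower. Sharing was examined to tell lists of called cells, which would share few barcodes, from lists of every barcode seen, which would share many. With 68.07% of barcodes in all 3 lists, the lists were read as lists of every barcode seen. The length of a list is therefore not a number of cells.

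Sharing was set against that of independent lists from the pool estimated from all 3. The ratio of observed to expected shared barcodes was 1.0056 (95% interval 1.0049 to 1.0064) for allo-spleen and graft. It was 1.0053 (1.0043 to 1.0063) for graft and iso-spleen, and 1.0108 (1.0098 to 1.0119) for both spleens. For all 3 lists it was 1.0247 (1.0234 to 1.026), an excess of 12007.5 barcodes over the 486481.5 expected. The pool was fitted so that the expected number of distinct barcodes equals the observed one. The excess in all 3 lists therefore equals the summed excesses of the 3 pairs by construction, and is no separate result. The ratios depended on the pool by more than their intervals. With the pool estimated from both spleen lists alone, 725812 barcodes, the ratio for all 3 lists was 1.0028 and the excess 1394.2 barcodes, and the ratios of the graft list with the allo-spleen and iso-spleen lists fell below 1, to 0.9948 and 0.9945. That pool is smaller than the 732317 distinct barcodes listed, so it cannot be the full pool. With the pool taken as those 732317 barcodes, the smallest that can hold them, the ratio for all 3 lists was 1.0209.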

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

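The lengths of the lists, the number of genes and the 97 listed genes found were the same or within 1.5 times under the alternatives run for them. These alternatives had little room to change the gene counts, so they are a weak check. Matching without regard to case can only add genes, up to the 99 fixed, and only 78 rows carried a repeated symbol. With the pool taken as the union of 732317 barcodes, the observed-to-expected ratios were 1.0038 for allo-spleen and graft, 1.0034 for graft and iso-spleen, 1.009 for both spleens and 1.0209 for all 3 lists. Pools estimated from a single pair held 729576 barcodes (allo-spleen and graft), 729826 (graft and iso-spleen) and 725812 (both spleens), each fewer than the union, and gave ratios of 1.0132, 1.0139 and 1.0028 for all 3 lists. Of the pair ratios, 3 turned below 1: graft and iso-spleen at 0.9997 with the pool of allo-spleen and graft and at 0.9945 with that of both spleens, and allo-spleen and graft at 0.9948 with that of both spleens. The others were 1.0003 for allo-spleen and graft with the pool of graft and iso-spleen, and 1.0052 and 1.0055 for both spleens with the pools of allo-spleen and graft and of graft and iso-spleen. A pair's own pool makes its ratio 1 by construction, so none is given. Ratios from barcodes split by first base lay within the intervals of the main values, whose width is approximate. The alternatives planned for expression values were not run, since no such values were analysed. No paired analysis was possible because each group has 1 library. The unknown depth prevents any statement on expression or cell numbers.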

Other observations

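Gene types separated sharply in the feature lists. All 144 variable-segment genes of T cell receptors (type TR_V_gene) and all 218 of antibodies (type IG_V_gene) in M21 had a row. So did all 34 variable-segment pseudogenes of T cell receptors and all 158 of antibodies. None of 2207 microRNA genes, 1507 small nucleolar RNA genes or 2 mitochondrial ribosomal RNA genes had one, and 1 of 9941 processed pseudogenes did.

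The tests on base composition and on gene types were set before their results, except that pools from single pairs within G+C counts were added after the data were seen. The alpha chain gene of H2-E may have no row because the authors' annotation kept only some gene types. M21 holds no gene named H2-Ea, so the type tested is that of H2-Ea-ps. This hypothesis needs the other genes of that type in M21 to be missing too. Of the 81 other polymorphic pseudogenes, 0.0% had a row (exact 95% interval 0.0 to 4.45%), against 98.52% of protein-coding genes. The test fits this hypothesis. Whatever the reason, neither H2-Ea nor H2-Ea-ps had a row, so transcripts of the H2-E alpha chain from donor cells in the graft would have had no gene of their own to be counted under. Whether such transcripts were present was not tested.

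More barcodes stood in all 3 lists than independent lists would share, by 12007.5 barcodes with the pool estimated from all 3 lists. That pool makes this excess equal to the summed excesses of the 3 pairs. The excess was 1394.2 with the pool from both spleen lists alone, which is too small to hold the 732317 distinct barcodes listed. With those 732317 barcodes as the pool, the observed-to-expected ratio for all 3 lists was 1.0209. An uneven yield of barcodes by base composition is a candidate explanation. The share of barcodes found in all 3 lists was 65.1% for those with 5 G or C bases and 71.59% for those with 11. Fitting a pool for each G+C count removed 1.09% of the excess with pools from all 3 lists, leaving 11877.2 barcodes. Under 25% had been set in advance as the mark against this explanation. The value argues against G+C count as the cause of more than a small part of the excess. The same fit removed 0.96% to 2.27% with pools from single pairs, which over all barcodes were smaller than the union. An uneven yield for other reasons stays open and was not tested, and no biological explanation was tested, since the design names none for barcodes.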
